A study of Mus musculus with 10 samples.

How the data were processed

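RNA sequencing was done on total RNA of clone 4T1-T, a clonal population grown out of the mouse mammary carcinoma line 4T1. Per the labels' protocols, cells were kept in DMEM with 5% fetal bovine and 5% fetal calf serum, and RNA was purified on columns with a DNase step. From 100 ng of total RNA, cDNA was amplified with the NuGEN Ovation RNA-Seq V2 kit, sheared to about 200 bp and sequenced with 76 bp reads. The 10 libraries fall into 5 groups of 2 libraries (A and B), which carry a hairpin against Renilla luciferase (shRenilla, the control), 1 of 2 hairpins against Serpine2, or 1 of 2 hairpins against Slpi. Groups and letters were taken from the sample titles.

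The deposited table holds log2 values for 23479 gene entries. Per the submitters' processing notes, Bowtie2, HTSeq and DESeq were used with genome build mm10. Versions, settings, annotation and filters are not given in the sources used here, nor is whether counting used strand. From the values themselves, each column starts at a floor of 6.733366499 and the highest value is 20.4, which is the form of the variance-stabilizing transformation of DESeq, the package the submitters name. Inverting that transformation gave normalized counts that were whole multiples of 1 step in each library, and dividing by the step gave read counts, of which 100% were whole within 0.01 reads. The transformation flattens differences among weakly expressed genes, so the inverted normalized counts were used. The inversion rests on the values, and no label states the transformation.

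Recovered depth was 15877431 to 24026620 reads per library. A count of 0 leaves room for up to 3 reads, which is 2.30 to 3.48 normalized reads depending on the library, and such floors cover counting error only, since amplified reads are not independent molecules. Libraries of a group differed by more than counting noise, with a chi-square per degree of freedom of 10.9 in shSlpi-2 and 1.55 to 2.76 in the other groups. No library was a copy of another. No entry lacked a gene name. Names of 27 entries had been turned into dates by spreadsheet software. They stayed in the tests and are not named. The table had 22241 genes with at least 1 read, and 1238 were at 0 in every library. Gene positions are those of GENCODE M21 on GRCm38, in which 21845 symbols matched once.

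Tests were made on log2(normalized count + 1) with limma 3.58.1 in R 4.3.3, using eBayes with a mean-variance trend. The 12299 genes with a mean of at least 10 entered a fit of 5 group means over the 10 libraries, so that all groups shared their estimate of the spread. Since the shSlpi-2 libraries differed most, that estimate leans low for shSlpi-2 and high for the other groups. Fold changes are on this log2(value + 1) scale, which understates changes of weakly expressed genes. P-values are two-sided and were adjusted with the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 are said to have risen, fallen or changed. The planned test was the same fit on the deposited normalized values. Since the table held transformed values, these were inverted first and the test was then run as planned.

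Contrasts were the mean of both Serpine2 hairpins against shRenilla, the same for Slpi, each hairpin alone, Serpine2 hairpins against Slpi hairpins, and hairpin against hairpin for each target. Named genes were chosen by a rule. For each knockdown it took the target and the 10 genes with the largest rise and the 10 with the largest fall among changed genes with a mean of at least 50, the same sign with both hairpins and all 4 knockdown libraries on the same side of both shRenilla libraries. For Serpine2 against Slpi it took 5 and 5, for each pair of hairpins 3 and 3, and for each gene list up to 4 changed members with the smallest p. Gene models without a proper name were counted but not named, and the values of some genes that the rule takes are not reported here.

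The 24 gene lists covered protease inhibitors, coagulation and fibrinolysis, extracellular and lysosomal proteases, basement membrane, mesenchymal state, epithelial state, vascular mimicry literature, secreted angiogenic factors, markers of endothelial cells, leukocytes and fibroblasts, interferon-stimulated genes, NF-kB and inflammatory cytokines, cell cycle, p53 target genes, the unfolded protein and integrated stress response, hypoxia and glycolysis, cholesterol and fatty acid synthesis, Nrf2 antioxidant genes, YAP and TGF-beta target genes, immediate early and ERK target genes, cytosolic ribosomal proteins, mitochondrially encoded genes and replication-dependent histones. The mitochondrially encoded list has 15 genes, of which 0 were measured, and it gave no result. The other lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, and again with the correlation estimated for each list. Members were counted after adjustment over all 12299 genes and adjusted over the list alone. The groups, contrasts, tests, naming rule, gene lists and the first set of other settings below were fixed before the data were examined.

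The test was checked on simulated data for the Serpine2 knockdown against shRenilla, in which 50 of the 12299 genes were changed at each size of fold. It recovered 70.0% of genes changed 1.25-fold, 96.0% of those changed 1.5-fold and 100% of those changed 2-fold or 4-fold. Of its calls, 6.15% were unchanged genes. The simulated counts had the same dispersion (0.0013) for every gene and group. These shares therefore hold for an equal spread, while the real groups differed in spread. For overlaps between contrasts that share the shRenilla libraries, 100 sets of unchanged groups were simulated.

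Other settings tried were pseudocounts of 0.5 and 5, no filter, a minimum mean of 50, quantile normalization, recomputed median-of-ratios scaling, only the libraries compared, the replicate letter as a block, a robust variance prior, an absolute log2 fold change of at least 1, an estimated list correlation and leaving out each library in turn. Chosen after seeing the data were the deposited values as they stand, limma's voom on the recovered reads, subtraction of the read density over silent receptor genes, hairpin lines as units, 1 shRenilla library as the control of each knockdown for their shared calls, and leaving out both shSlpi-2 libraries, for lists also with an estimated correlation. Without the shSlpi-2 libraries, Slpi knockdown is shSlpi-1 alone, and the shared estimate of the spread changes too. Silent receptor genes are olfactory and vomeronasal receptor genes, of which 1421 with few reads were used, and their read density is in reads per kb of coding sequence. Exonic lengths for the subtraction were found for 94.0% of tested genes. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Sequencing batches are not given in the labels.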

Results

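Transcriptomes of clone 4T1-T were measured in cells carrying a control hairpin (shRenilla) or hairpins that lower Serpine2 or Slpi. 4T1 is a mouse mammary carcinoma line that spreads from its site of growth to distant organs, and 4T1-T is a clone grown from a single cell of it. Serpine2 (protease nexin-1) is a secreted inhibitor of thrombin, urokinase and other serine proteases, and Slpi (secretory leukocyte protease inhibitor) is a secreted inhibitor of neutrophil elastase and related proteases. The series is about tumour heterogeneity, metastasis and vascular mimicry, in which tumour cells line blood-carrying channels. The comparisons here ask which transcripts differ in this clone when either inhibitor is lowered. Each of the 5 groups had 2 libraries, and depth ran from 15877431 reads (shSerpine2-1, library B) to 24026620 reads (shSerpine2-2, library B). Nothing in the labels says that libraries A and B came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Values below are mean normalized read counts ± SD over the 2 libraries of a group, and fold changes are given on the log2 scale with their standard error (SE) and limma's adjusted p.

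Serpine2, on the minus strand of chromosome 1 from 79794197 to 79861180 (GRCm38), stood at 3201 ± 79.1 (SD, n = 2) in shRenilla. It was 134 ± 7.94 with shSerpine2-1 and 501 ± 17.5 with shSerpine2-2, which is 23.8-fold and 6.37-fold lower. Over both hairpins the log2 fold change was -3.62 (SE 0.06, limma adjusted p = 2.01e-16). Slpi, on the minus strand of chromosome 2 from 164354070 to 164389095, fell from 1251 ± 87.6 in shRenilla to 146 ± 1.09 with shSlpi-1 and 68.3 ± 10.5 with shSlpi-2, 8.51-fold and 18.1-fold lower. Over both hairpins the log2 fold change was -3.64 (SE 0.10, limma adjusted p = 5.05e-13).

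Each inhibitor was also lower in lines silenced for the other, apart from Slpi with shSerpine2-2. Serpine2 was 1336 ± 7.76 with shSlpi-1 and 1642 ± 126 with shSlpi-2 (log2 fold change over both -1.11, SE 0.06, limma adjusted p = 2.51e-09). Slpi was 370 ± 62.3 with shSerpine2-1 (log2 fold change -1.76, SE 0.12, limma adjusted p = 1.96e-07). With shSerpine2-2 it was 1164 ± 75.6 (log2 fold change -0.10, limma adjusted p = 0.554), and the difference between the 2 Serpine2 hairpins was -1.66 (adjusted p = 4.13e-07).

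**Figure D1:**
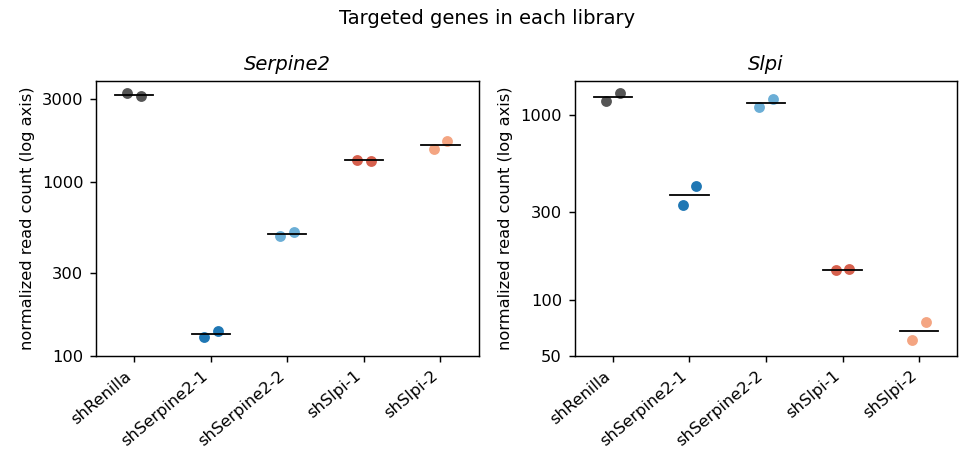
Normalized read counts of Serpine2 (left) and Slpi (right) on log axes in each of the 10 libraries, by group; points are libraries and horizontal lines are group means. Serpine2 has its lowest mean in shSerpine2-1 (134) and Slpi in shSlpi-2 (68.3), and Slpi is also low in shSerpine2-1 (370).

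With Serpine2 lowered, the named genes that rose include Krt14, Krt7 and Slc7a11, and those that fell include Ace, Dmp1 and Tslp. Krt14, a keratin of basal epithelium, rose from 117 ± 3.72 in shRenilla to 218 ± 2.36 with shSerpine2-1 and 255 ± 15.3 with shSerpine2-2 (log2 fold change 1.00, SE 0.10, adjusted p = 8.16e-06). Slc7a11, the cystine importer that feeds glutathione synthesis, rose from 587 ± 13.3 to 887 ± 46.9 and 1126 ± 55.0 (log2 fold change 0.77, SE 0.06). Ace, the angiotensin-converting enzyme, fell from 141 ± 10.6 to 23.2 ± 8.16 and 56.3 ± 4.86 (log2 fold change -1.96, SE 0.27, adjusted p = 1.23e-04). Tslp, an epithelial cytokine, fell from 1557 ± 35.6 to 614 ± 6.14 and 1025 ± 19.7 (log2 fold change -0.97, SE 0.09). Other rises were those of Mal (0.98) and Mal2 (0.70), proteolipids of membrane traffic, Chac1 (0.74), which degrades glutathione, Gpt2 (0.71), a mitochondrial alanine aminotransferase, Krt7 (0.68), a keratin of simple epithelium, Frmd4b (0.71) and Cyb561d2 (0.68). Other falls were those of Dmp1 (-1.26), a mineralization protein, Enpp2 (-1.22), the enzyme that makes lysophosphatidic acid, Mertk (-1.06), a receptor kinase that binds dying cells, Man1c1 (-0.98), a Golgi mannosidase, Abcc3 (-0.97), an export pump, Unc13c (-1.07), AW046200 (-1.07) and Gpr123 (-1.02). Among these genes, the call of Mertk ended without shRenilla library A (-0.94, adjusted p = 0.0529) and that of Frmd4b without shRenilla library B (0.65, adjusted p = 0.0595).

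In all, 2643 of 12299 genes changed with Serpine2 lowered, 1311 up and 1332 down, with a median change of 1.20-fold, and 50 of them changed by at least 1 on the log2 scale. Of the naming rule's criteria, 1178 rising and 1121 falling genes met all. With hairpin lines as units, so that the spread was that between the 2 hairpins of a target, limma called 0 genes (499 had an unadjusted p under 0.05) and did not call Serpine2 itself (adjusted p = 0.932). The count was 1393 without shRenilla library A, 766 without shRenilla library B, 1632 with no filter on low counts and 4176 with only the 6 compared libraries in the fit.

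Gene lists of epithelium and of lipid synthesis rose with Serpine2 lowered. Of 41 measured epithelial genes, 18 rose, 0 fell and 23 did not pass (19 and 0 adjusted over the list alone; camera adjusted p = 2.76e-07, and adjusted p = 0.0101 with an estimated correlation). Cdh1, which encodes E-cadherin, rose by 0.31 (SE 0.04) and Cgn, a tight junction protein, by 0.51 (SE 0.06). Of 33 genes of cholesterol and fatty acid synthesis, 25 rose, 0 fell and 8 did not pass (27 and 0 adjusted over the list alone; camera adjusted p = 2.02e-15, and adjusted p = 0.00485 with an estimated correlation). They include Fasn (0.32, SE 0.04), the fatty acid synthase, and Hmgcs1 (0.34, SE 0.05), an early enzyme of the sterol pathway.

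Of 40 genes of the unfolded protein and integrated stress response, 20 rose, 2 fell and 18 did not pass (21 and 2 adjusted over the list alone; camera adjusted p = 1.00e-08, and adjusted p = 0.0101 with an estimated correlation), with a median of 0.09 with shSerpine2-1 and 0.31 with shSerpine2-2. The members with the smallest p were Slc7a11, the large neutral amino acid transporter Slc7a5 (0.53, SE 0.05), asparagine synthetase Asns (0.54, SE 0.05) and the folate enzyme Mthfd2 (0.58, SE 0.06). These serve amino acid supply and are known targets of the transcription factor Atf4. With an estimated correlation only these 3 lists of the Serpine2 comparison, epithelial, lipid synthesis and stress response, kept their call.

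The other 7 lists called at the preset correlation lost the call with an estimated one. A higher correlation is not the reason for all of them. The estimates for the interferon (0.0046) and mesenchymal (0.0025) lists lay under the preset 0.01. So did those of the epithelial (-0.018) and lipid synthesis (-0.015) lists, whose adjusted p also rose. Loss of a call with an estimated correlation therefore does not by itself show that members of a list vary together. Among 57 cell cycle genes 18 rose and 2 fell (19 and 2 adjusted over the list alone; camera adjusted p = 3.08e-05, and adjusted p = 0.127 with an estimated correlation), with Cdca8 at 0.35, the helicase subunit Mcm3 at 0.28 and E2f1 at 0.49. Among 29 Nrf2 antioxidant genes 9 rose and 1 fell (12 and 2 adjusted over the list alone; camera adjusted p = 0.0233, and adjusted p = 0.263 with an estimated correlation). Among 75 ribosomal protein genes 11 rose and 0 fell (8 and 0 adjusted over the list alone; camera adjusted p = 3.75e-04, and adjusted p = 0.878 with an estimated correlation), with a median of 0.01 with shSerpine2-1 and 0.18 with shSerpine2-2. Ribosomal protein genes may share reads with pseudogenes. Among 50 replication-dependent histone genes 0 rose and 21 fell (0 and 33 adjusted over the list alone; camera adjusted p = 5.14e-11, and adjusted p = 0.504 with an estimated correlation). Histone genes such as Hist1h1c (-0.39, SE 0.07) have close copies, so reads may be split among them.

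Among 54 interferon-stimulated genes 2 rose and 7 fell (the same numbers adjusted over the list alone; camera adjusted p = 0.0166, and adjusted p = 0.127 with an estimated correlation), with Oasl2 at -0.59 (SE 0.09) and Ifi44 at -1.35 (SE 0.21). Among 28 mesenchymal genes 1 rose and 7 fell (the same numbers adjusted over the list alone; camera adjusted p = 0.0233, and adjusted p = 0.138 with an estimated correlation). Those that fell include Spp1 (-0.85, SE 0.04), the secreted phosphoprotein osteopontin, and Acta2 (-1.18, SE 0.21), smooth muscle actin. Acta2, Ifi44 and, below, Egr2 were named as list members, and none of them met all criteria that the naming rule set for single genes. The mesenchymal list was not called without shRenilla library A (adjusted p = 0.0617). Among 37 immediate early and ERK target genes 5 rose and 12 fell (5 and 15 adjusted over the list alone; camera adjusted p = 0.0239, and adjusted p = 0.504 with an estimated correlation), with the phosphatase gene Dusp6 at -0.48 (SE 0.06) and the transcription factor gene Egr2 at -1.30 (SE 0.21). That list was not called without shRenilla library B (adjusted p = 0.0697).

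Lists near the function of Serpine2 held genes that went both ways and were not called. Among 18 protease inhibitors 5 rose and 2 fell (camera adjusted p = 0.846), with Reck, an inhibitor of matrix metalloproteinases, at -0.64 (SE 0.09). Among 21 genes of coagulation and fibrinolysis 6 rose and 3 fell (camera adjusted p = 0.846), with thrombospondin gene Thbs1 at 0.52 (SE 0.05) and Plat, the tissue plasminogen activator, at -0.64 (SE 0.13). Among 36 extracellular and lysosomal proteases 9 rose and 7 fell (10 and 8 adjusted over the list alone; camera adjusted p = 0.884), with Mmp3 at -0.60 and Adamts1 at 0.41. Among 23 basement membrane genes 8 rose and 2 fell (camera adjusted p = 0.0801). Counts adjusted over the list alone were the same for the inhibitor, coagulation and basement membrane lists. The vascular mimicry list had 4 rises and 2 falls among 25 genes (4 and 3 adjusted over the list alone; camera adjusted p = 0.917), with the semaphorin and VEGF receptor Nrp2 at 0.34 (SE 0.04). The list of secreted angiogenic factors had 5 rises and 6 falls among 30 genes (6 and 7 adjusted over the list alone; camera adjusted p = 0.884), with the growth factor gene Tgfa at -0.47 and the matricellular Cyr61 at 0.37. Medians of the inhibitor (-0.02), coagulation (-0.06) and protease (-0.03) lists were below 0 while camera pointed up, and the inhibitor median was 0.02 under quantile normalization.

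With Slpi lowered, Krt14 and Tslp changed in the same directions as with Serpine2 lowered and, as means over both hairpins, by more, with differences (Serpine2 minus Slpi) of -0.76 (SE 0.08, limma adjusted p = 1.37e-05) and 0.91 (SE 0.07, limma adjusted p = 3.69e-07). For Tslp single lines overlapped, with 618 and 610 in the shSerpine2-1 libraries and 647 and 583 in the shSlpi-1 libraries. Krt14 rose to 315 ± 44.4 with shSlpi-1 and 507 ± 52.0 with shSlpi-2 (log2 fold change 1.75, SE 0.10, adjusted p = 3.28e-09). Fgfbp1, a carrier that releases fibroblast growth factors from the matrix, rose from 1431 ± 7.25 to 2825 ± 25.9 and 2831 ± 139 (log2 fold change 0.98, SE 0.05). Spp1, the osteopontin gene, fell from 24485 ± 1615 in shRenilla to 11365 ± 146 with shSlpi-1 and 7298 ± 204 with shSlpi-2 (log2 fold change -1.43, SE 0.04, adjusted p = 7.56e-13). Tslp fell to 615 ± 45.6 and 293 ± 58.0 (log2 fold change -1.88, SE 0.09). Other rises were those of Itgb6 (1.14), an epithelial integrin chain, Edn1 (1.11), the peptide endothelin-1, Ctsw (0.96), a cathepsin, Mal (0.96) and AU018091 (1.06). Other falls were those of Ace (-2.57), Cck (-2.13), the peptide cholecystokinin, Dmp1 (-1.93), Man1c1 (-1.75), Mgp (-1.51), an inhibitor of calcification, Fgfr1 (-1.45), a fibroblast growth factor receptor, Angpt1 (-1.39), a ligand of the Tie2 receptor, and Mertk (-1.34). The rule also named Lars2 (2.38) and Rn45s (1.76), the precursor of ribosomal RNA, for both of which the reads are uncertain. They were highest in the 2 shSlpi-2 libraries, where Rn45s took 6.88% and 6.91% of reads against 1.00% and 1.21% in shRenilla.

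In all, 4281 of 12299 genes changed with Slpi lowered, 2027 up and 2254 down (3001 up and 1936 down with no filter on low counts), with a median change of 1.24-fold, and 142 of them changed by at least 1 on the log2 scale. All criteria of the naming rule were met by 1651 rising and 1822 falling genes. With hairpin lines as units limma called 0 genes (1281 had an unadjusted p under 0.05) and did not call Slpi itself (adjusted p = 0.324). The count was 2732 without shRenilla library A and 2401 without shRenilla library B, and without both shSlpi-2 libraries it was 3323, of which 2651 were called in the same direction with all libraries.

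**Figure D2:**
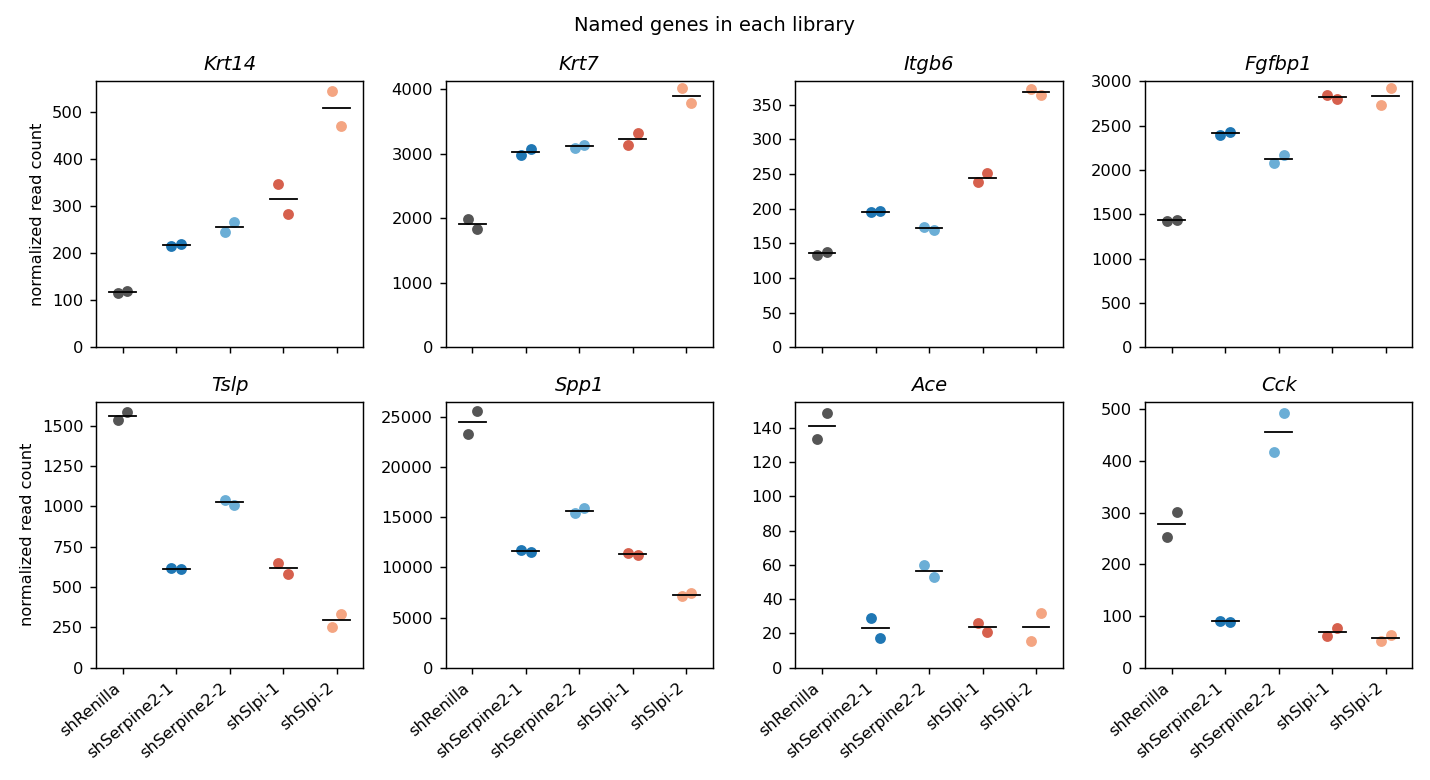
Normalized read counts of 8 named genes (y axes, linear from 0) in each library, by group; points are libraries and horizontal lines are group means. Krt14, Krt7, Itgb6 and Fgfbp1 lie above shRenilla and Tslp, Spp1 and Ace below it in all 4 knockdown lines, while Cck is 456 with shSerpine2-2 and at most 90.4 in the other knockdown lines.

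Epithelial, lipid synthesis and stress response genes also rose with Slpi lowered, the 3 lists that kept their call with an estimated correlation in this comparison. Of 41 epithelial genes, 26 rose, 0 fell and 15 did not pass (29 and 1 adjusted over the list alone; camera adjusted p = 5.43e-12, and adjusted p = 0.00411 with an estimated correlation), with Krt7 at 0.89 (SE 0.05) and the adhesion molecule gene Epcam at 0.59 (SE 0.05). Of 33 lipid synthesis genes, 27 rose, 0 fell and 6 did not pass (the same numbers adjusted over the list alone; camera adjusted p = 2.15e-15, and adjusted p = 0.00411 with an estimated correlation), with the desaturase gene Scd2 at 0.56 (SE 0.04) and Cyp51 of the sterol pathway at 0.50. Of 40 stress response genes, 19 rose, 4 fell and 17 did not pass (20 and 4 adjusted over the list alone; camera adjusted p = 1.07e-04, and adjusted p = 0.0428 with an estimated correlation), with Slc7a5 at 0.47 and the chaperone partner Dnajb11 at 0.42. Without both shSlpi-2 libraries the stress response list was not called with an estimated correlation (adjusted p = 0.283).

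Of 75 ribosomal protein genes, 46 rose and 1 fell (50 and 2 adjusted over the list alone; camera adjusted p = 2.50e-10, and adjusted p = 0.664 with an estimated correlation), with Rps14 at 0.70 (SE 0.08). Of 37 immediate early and ERK target genes, 7 rose and 16 fell (the same numbers adjusted over the list alone; camera adjusted p = 0.0199, and adjusted p = 0.557 with an estimated correlation). Those that fell include Egr1 (-1.15, SE 0.08), Dusp6 (-0.73, SE 0.06) and Spred1 (-0.48, SE 0.04), a brake on Ras signalling. The list was not called without shSlpi-2 library A. Without both shSlpi-2 libraries it was called in the same direction (camera adjusted p = 4.67e-04), but not with an estimated correlation (camera adjusted p = 0.285). Histone genes were called with 6 falls among 50 (0 adjusted over the list alone; camera adjusted p = 0.0101, and adjusted p = 0.740 with an estimated correlation), but their median was -0.44 with shSlpi-1 and 0.05 with shSlpi-2. That call ended without shRenilla library B, shSlpi-1 library B or shSlpi-2 library A. Without both shSlpi-2 libraries the histone list was called, pointing down (camera adjusted p = 4.12e-15), but not with an estimated correlation (camera adjusted p = 0.383).

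The remaining lists were not called for Slpi. Among 18 protease inhibitors 6 rose and 3 fell (the same numbers adjusted over the list alone; camera adjusted p = 0.471), with Serpinb5, known as maspin, at 0.92 (SE 0.11), Serpinb9 at -0.93 (SE 0.10) and Reck at -0.88 (SE 0.09). Among 36 extracellular and lysosomal proteases 9 rose and 9 fell (10 and 14 adjusted over the list alone; camera adjusted p = 0.579). The stromelysin gene Mmp3 fell from 816 ± 40.3 to 375 ± 25.8 and 317 ± 4.61, while the metalloproteinase genes Adam12 (0.77, SE 0.05) and Adamts1 (0.76, SE 0.05) rose. Among 21 coagulation genes 6 rose and 5 fell (7 and 5 adjusted over the list alone; camera adjusted p = 0.630), with Thbs1 at 0.42 and the thrombin receptor gene F2r at -0.27. Among 25 vascular mimicry genes 5 rose and 5 fell (the same numbers adjusted over the list alone; camera adjusted p = 0.721), with the Notch ligand gene Dll4 at -0.90 (SE 0.13). Among 30 secreted angiogenic factors 7 rose and 8 fell (8 and 8 adjusted over the list alone; camera adjusted p = 0.859), with Ctgf at 0.75, Cyr61 at 0.65 and Tgfa at -0.96. Among 28 mesenchymal genes 2 rose and 9 fell (the same numbers adjusted over the list alone; camera adjusted p = 0.0592), with Zeb2 at -0.41 and Tpm1 at 0.34. Means of the coagulation (-0.05), protease (-0.07) and secreted angiogenic (-0.03) lists were below 0 while camera pointed up. The secreted angiogenic median of 0.02 became -0.007 under quantile normalization.

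**Figure D3:**
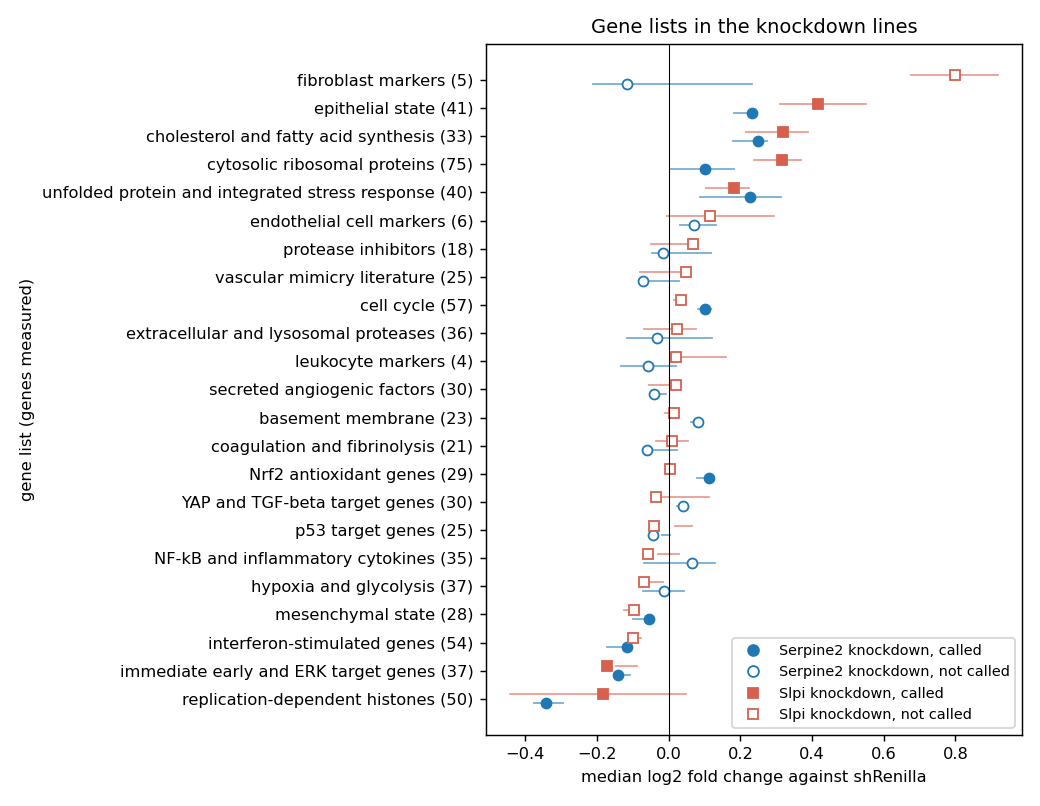
Median log2 fold change against shRenilla (x axis) of each gene list (y axis, number of measured genes in brackets) for Serpine2 knockdown (circles) and Slpi knockdown (squares); filled symbols are lists called by camera at the preset correlation, and lines span the medians of the 2 hairpins. Epithelial genes have medians of 0.23 and 0.42 and lipid synthesis genes of 0.25 and 0.32, while the histone line for Slpi spans -0.44 to 0.05.

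Serpine2 knockdown was also set directly against Slpi knockdown, a comparison without the shRenilla libraries. Apart from the targets, Cck (1.69, SE 0.11), Cyp1b1 (0.95, SE 0.04), Fgfr1 (0.93, SE 0.09) and Prl2c2 (0.90, SE 0.11) were higher in the Serpine2 lines than in the Slpi lines. Cyp1b1 is a cytochrome P450 that oxidizes estrogens. Prl2c2 is a member of a family of near-identical genes and so uncertain. Lars2 (-2.08), Rn45s (-1.57), the mucin gene Muc6 (-1.04, SE 0.10) and the collagen gene Col14a1 (-0.91, SE 0.13) were lower in the Serpine2 lines. Cyp1b1 was 2078 ± 57.3 and 3169 ± 199 with the Serpine2 hairpins and 1756 ± 46.2 and 1004 ± 38.8 with the Slpi hairpins. Some of these differences were small between shSerpine2-1 and shSlpi-1 and larger with shSerpine2-2, where Slpi was near shRenilla. Prl2c2 was 173 and 205 in shSerpine2-1 and 167 and 163 in shSlpi-1, against 345 and 392 in shSerpine2-2. Muc6 was 143 and 182 in shSerpine2-1 and 193 and 183 in shSlpi-1, against 69.4 and 70.5 in shSerpine2-2. In all, 2157 genes differed, 1270 higher and 887 lower with Serpine2 lowered (1024 higher and 1648 lower with no filter on low counts, 925 and 858 under quantile normalization), with a median difference of 1.16-fold, and the rule's criteria were met by 545 and 200. Without both shSlpi-2 libraries 2116 genes differed, of which 922 were called in the same direction with all libraries and 14 in the opposite one.

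Epithelial genes were lower in the Serpine2 lines than in the Slpi lines (1 higher and 19 lower of 41, or 1 and 23 adjusted over the list alone; camera adjusted p = 5.24e-10, and adjusted p = 0.0119 with an estimated correlation), with Itgb6 at -0.71 and Epcam at -0.30. Without both shSlpi-2 libraries that list was called at the preset correlation (adjusted p = 0.00971) and not with an estimated one (adjusted p = 0.169). Nrf2 antioxidant genes were higher (12 and 0 of 29, or 14 and 2 adjusted over the list alone; camera adjusted p = 1.99e-05, and adjusted p = 0.0844 with an estimated correlation), with the glutathione transferase gene Gsta4 at 0.69, Slc7a11 at 0.60 and Hmox1, heme oxygenase, at 0.47. Ribosomal protein genes were lower (3 and 28 of 75, or 4 and 36 adjusted over the list alone; camera adjusted p = 1.42e-08, and adjusted p = 0.626 with an estimated correlation). Lipid synthesis genes were lower (0 and 9 of 33, the same adjusted over the list alone; camera adjusted p = 3.89e-04, and adjusted p = 0.0725 with an estimated correlation), and their call ended without both shSlpi-2 libraries (adjusted p = 0.728). The call of histone genes (0 and 8 of 50, or 0 and 10 adjusted over the list alone; camera adjusted p = 2.44e-05, and adjusted p = 0.696 with an estimated correlation) also ended without both (adjusted p = 0.121, pointing up) and without shSlpi-2 library B alone (adjusted p = 0.103). With hairpin lines as units limma called 0 genes (419 had an unadjusted p under 0.05). The count of genes was 1174 or 1342 without shSerpine2-1 library A or B, 1106 or 1415 without shSerpine2-2 library A or B, 1314 without shSlpi-1 library A and 3436 without shSlpi-2 library A.

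Many genes were called in the same direction after both knockdowns. Of the genes called in both, 973 rose in both (216 for independent lists), 1075 fell in both (244 for independent lists) and 8 went opposite ways (460 for independent lists). Among them are Krt14, Krt7 and Mal, which rose, and Ace, Dmp1, Tslp, Man1c1 and Mertk, which fell. Both comparisons use the same shRenilla libraries, and unchanged groups simulated against them shared 0.12 calls on average and at most 2, a number near 0 by construction, since unchanged groups give few calls. Across genes, which are not independent replicates, the fold changes correlated at 0.735 against 0.668 in the simulation, and their covariance was 0.0619 against 0.0141. With shRenilla library A as the control for Serpine2 and library B for Slpi, chosen after the data were seen, 604 genes were called in the same direction (310 up and 294 down, against 41.0 and 43.6 for independent lists), and the covariance was 0.0502. With the libraries exchanged the count was 836 (363 up and 473 down, against 64.9 and 71.1 for independent lists) and the covariance 0.0464. Both are libraries of 1 control line, which the knockdowns then still share. The shared count of 2048 was 1113 without shRenilla library A, 631 without shRenilla library B, 1342 with no filter and 0 with hairpin lines as units.

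**Figure D4:**
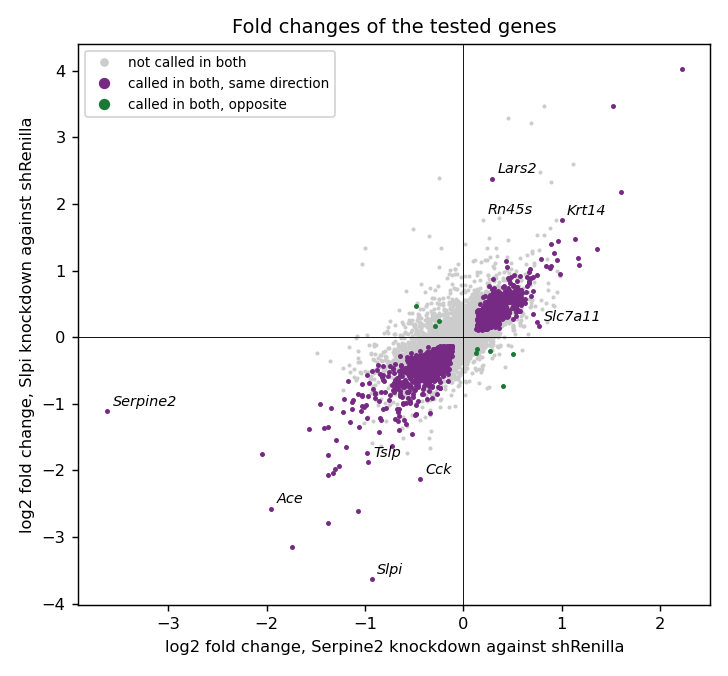
Log2 fold change against shRenilla of each tested gene after Serpine2 knockdown (x axis) and Slpi knockdown (y axis); purple genes were called in both in the same direction, green genes in opposite directions. Of the genes called in both, 2048 share their direction and 8 do not.

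Hairpins against the same target differed in many genes. Between the Serpine2 hairpins Cck (-2.32, SE 0.16) and Mgp (-1.66, SE 0.26) were lower with shSerpine2-1, and Nim1 (1.24), AU040972 (1.21) and Muc6 (1.19) were higher. Cck stood at 277 ± 34.7 in shRenilla, 90.4 ± 1.37 with shSerpine2-1 and 456 ± 53.2 with shSerpine2-2. Between the Slpi hairpins the gelatinase gene Mmp9 (-1.44, SE 0.11), Lars2 (-2.45) and Rn45s (-1.94) were lower with shSlpi-1, and Map1a (1.43), a microtubule protein, Shcbp1l (1.44) and the long noncoding RNA Fendrr (1.41) were higher. Mmp9 stood at 332 ± 3.94 in shRenilla, 214 ± 25.1 with shSlpi-1 and 584 ± 50.4 with shSlpi-2. Rn45s came to a difference of 0 between the Slpi hairpins under quantile normalization, which gives the highest gene the same value in every library. In all, 1805 genes differed between the Serpine2 hairpins (859 higher and 946 lower with shSerpine2-1) and 3204 between the Slpi hairpins (1687 higher and 1517 lower with shSlpi-1, or 1367 and 1953 with no filter). The first count was 498 or 635 without shSerpine2-1 library A or B, 696 or 404 without shSerpine2-2 library A or B, 3180 or 3181 without shSlpi-2 library A or B, 3599 with only the libraries compared and 1133 with no filter, and the second was 1539 without shSlpi-1 library B and 1252 with only the libraries compared.

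Genes such as Tslp, Ace and Krt14 changed with each hairpin alone, and 798 genes were called with both Serpine2 hairpins in the same direction (421 up and 377 down, against 88.6 and 88.4 for independent lists, with 23 opposite). For Slpi the number was 1647 (754 up and 893 down, against 192 and 267 for independent lists, with 31 opposite). Simulated unchanged groups, which give few calls by construction, shared 0.02 and 0.03 on average. Across genes, the fold changes of the Serpine2 hairpins correlated at 0.517, within the range of simulated unchanged groups (mean 0.503, highest 0.532). Their covariance of 0.0446 lay above the highest simulated one (0.0154). With Serpine2 and Slpi left out it was 0.0436, while pairs of a Serpine2 and a Slpi hairpin had 0.0438 to 0.0815. By this measure the Serpine2 hairpins shared no more with each other than with the Slpi hairpins. For the Slpi hairpins the correlation was 0.666 (highest simulated 0.541) and the covariance 0.0823 (highest simulated 0.0159). Alone, shSerpine2-1 changed 1288 genes (626 up), shSerpine2-2 3384 (1741 up), shSlpi-1 2156 (941 up) and shSlpi-2 5210 (2512 up and 2698 down, or 4862 and 2492 with no filter). Without shRenilla library A these 4 counts were 598, 2134, 1156 and 3931, and the both-hairpin counts were 370 for Serpine2 and 912 for Slpi. Without shRenilla library B they were 304, 1610, 814 and 3779, with 167 and 660. Leaving out library A or B of the line itself gave 392 and 377 for shSerpine2-1, 1843 and 1617 for shSerpine2-2, and 1258 and 919 for shSlpi-1. The Serpine2 both-hairpin count was then 258 or 238 without a shSerpine2-1 library and 444 or 454 without a shSerpine2-2 library, and the Slpi count 942 or 792 without a shSlpi-1 library. Leaving out shSlpi-2 library A or B gave 2435 and 2437 genes for shSerpine2-1, 3316 and 3320 for shSlpi-1, and 1547 and 1548 for both Serpine2 hairpins.

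Libraries differed in how many genes had reads. The numbers were 15887 and 16040 in shRenilla, 17841 and 17701 with shSerpine2-1, 15389 and 15630 with shSerpine2-2, 18366 and 17895 with shSlpi-1 and 19938 and 20253 with shSlpi-2. Over 1421 olfactory and vomeronasal receptor genes, which mammary cells are not known to use, read density was 0.152 ± 0.000921 reads per coding kb in shRenilla. It was 0.321 ± 0.0170 with shSerpine2-1, 0.110 ± 0.0193 with shSerpine2-2, 0.385 ± 0.0437 with shSlpi-1 and 1.02 ± 0.108 with shSlpi-2 (SD, n = 2). The 3 lines above shRenilla in this measure are those in which Slpi was called lower. Rn45s took 0.881% to 1.96% of reads in the 8 libraries other than shSlpi-2.

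**Figure D5:**
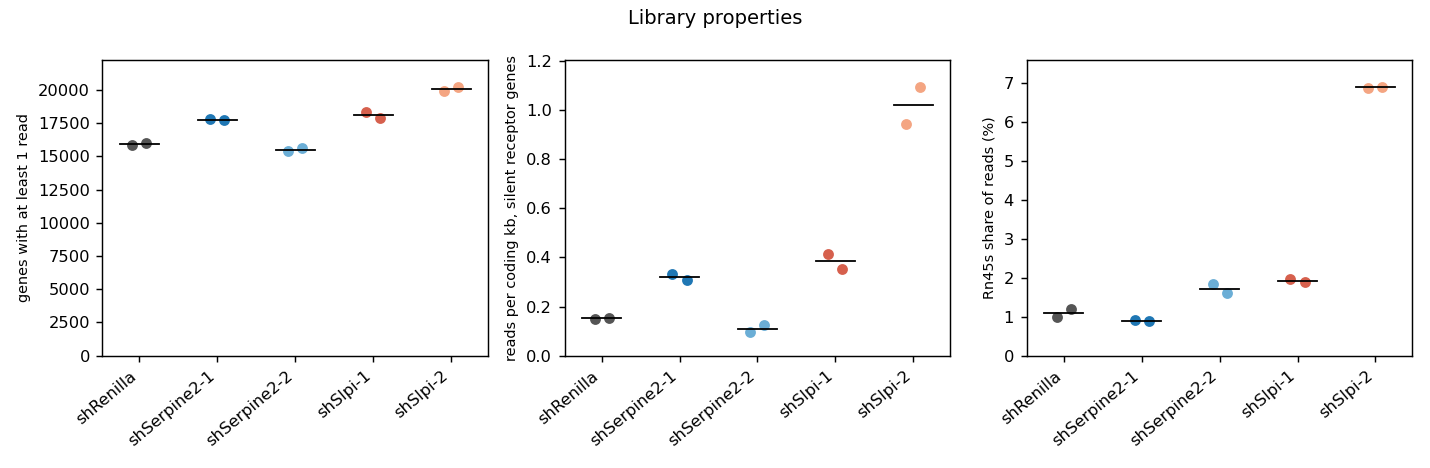
Number of genes with at least 1 read (left), reads per coding kb over silent receptor genes (middle) and share of reads on Rn45s in percent (right) in each library, by group; points are libraries and horizontal lines are group means, with all axes from 0. The 2 shSlpi-2 libraries are highest in all 3 panels.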

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

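Of the tests in this part, limma's contrasts and the search of Lars2 for ribosomal RNA words were planned, and the tests of receptor reads, thinned libraries, later ribosomal stretches, Rn45s between lines, covariances, genes called in all 4 lines and splits of the libraries were chosen only after the results were seen. Groups of 2 libraries are too small for a test of single outlying libraries.

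Hairpins against the same target differed by limma's test of the difference itself. For Serpine2, 1805 genes differed, with shSerpine2-1 above shSerpine2-2 by 1.24 in Nim1, 1.21 in AU040972 and 1.19 in Muc6 on the log2 scale, and differences of -2.32 in Cck, -1.90 in Serpine2, -1.66 in Mgp and -1.66 in Slpi. For Slpi, 3204 genes differed, with shSlpi-1 above shSlpi-2 by 1.44 in Shcbp1l, 1.43 in Map1a, 1.41 in Fendrr and 1.09 in Slpi, and differences of -2.45 in Lars2, -1.94 in Rn45s, -1.44 in Mmp9 and -0.29 in Serpine2. Reads over 1421 silent receptor genes, of which 3 had the mean count that the comparisons required and 1182 were tested with no filter, lay above shRenilla (0.152 per coding kb) at 0.321 in shSerpine2-1, 0.385 in shSlpi-1 and 1.02 in shSlpi-2.

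More genes had reads in the shSerpine2-1, shSlpi-1 and shSlpi-2 libraries than in shRenilla. Depth is argued against as the cause, since with every library thinned to the same total of reads the lowest of these 6 libraries still had 1733 more genes with reads than the higher shRenilla library. Genomic DNA is left open: the share of receptor genes with reads, over the share that evenly spread reads would give, was 0.808 and 0.834 in shSerpine2-1, 0.804 and 0.736 in shSlpi-1 and 0.773 and 0.758 in shSlpi-2, against 0.466 to 0.549 in shRenilla and shSerpine2-2, and the lowest of the 6 lies under the 0.75 set for an even spread. Against a fully even spread, the 5% of receptor genes with the most reads held 30.1% and 31.5% of the reads in shSlpi-2, where even draws give 18.8% and 19.3%, and per the labels the RNA was treated with DNase. A loss of Slpi that opens silent genes cannot be told apart from it, because receptor reads in shSerpine2-1, where Slpi was also lower, were 2.12 times those of shRenilla and genomic DNA would give the same.

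Rn45s and Lars2 reads were highest in the shSlpi-2 libraries, with 5.48 and 6.51 Lars2 reads per 100 Rn45s reads against 3.25 to 4.24 in the 8 other libraries. Ribosomal RNA carried into the libraries was tested by a search planned beforehand, which found 0 words of 25 bases shared by Lars2 and ribosomal RNA transcripts, the outcome set as arguing against it. That bound does not decide, since the search was incomplete: of 5 transcripts named for it, 4 were searched and the 18S gene was not, so the explanation stays open. Of 6 stretches tried later and taken as ribosomal from general knowledge, 1 of 21 bases, thought to be 28S, lies in 1 of 11588 genes searched, Lars2. None of the 6 was found in those 4 transcripts, so the identity of that stretch is unchecked. Whether 28S reads were counted as Lars2 cannot be told. A search for words of 25 bases could not find a shared stretch of 21 bases, with or without the 18S gene. A response to loss of Slpi in every line with lower Slpi is argued against. In shSerpine2-1 Rn45s lay at -0.27 (SE 0.08, log2) and Lars2 at -0.21 (SE 0.08) from shRenilla. A response to the lowest Slpi levels alone cannot be told apart from a difference between libraries, since 1 line has the lowest level. Against shSerpine2-2, in which Slpi was near shRenilla, Rn45s in shSlpi-1 was higher by 0.13 (SE 0.08), near its SE. Lars2 was higher by 0.35 (SE 0.08), several times its SE. Yet shSerpine2-2 itself lay above shRenilla. Its normalized Rn45s counts were 338797 and 297466 against 182077 and 221602, and its Lars2 counts 11719 and 11192 against 5977 and 7201.

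Many genes moved the same way after both knockdowns. Chance values of the shared shRenilla libraries are argued against as the whole cause, since the covariance of fold changes was 0.06195 and simulated unchanged groups reached at most 0.0153. A difference of the shRenilla line from all other lines is a candidate explanation. The excess covariance of lines with different targets was 0.979 of that of lines with 1 target. Single pairs were unequal. The covariance was lowest between the 2 Serpine2 hairpins (0.0436) and highest between shSerpine2-2 and shSlpi-2 (0.0815), which differ in target. A common response to losing either inhibitor cannot be told apart from a difference of the shRenilla line. Both would give genes called in 1 direction in all 4 lines, of which there were 498, and there is only 1 control line. Nor do the lines separate the inhibitors from each other. Serpine2 was also lower with both Slpi hairpins, and Slpi was also lower with shSerpine2-1.

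Other splits of the 8 knockdown libraries into 4 and 4 were set against Serpine2 knockdown and Slpi knockdown, in a fit of 2 groups without terms for hairpins. In that fit the real split called 0 genes by limma (1737 at an unadjusted p under 0.05), a count that all 35 of 35 splits reach by construction, so it tests nothing, and the highest other split called 1235. That highest split set shSerpine2-1 with shSlpi-1 against shSerpine2-2 with shSlpi-2 and points to a structure of the samples. The fit of 5 groups, which takes the difference between hairpins out of the spread, called 2157 genes for the real split, and 3956 had an unadjusted p under 0.05. For gene lists, 20 of 35 splits called as many as the real split, which called 5, with 9 in the highest other split. Of the 35 splits, 32 part the 2 libraries of a hairpin line. The 3 that keep lines whole, which called 5 lists (the real split), 8 and 5, are too few for a share under 0.05.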

How the results depend on the processing

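The fits on deposited values, voom, background subtraction, hairpin lines as units, separate controls and without both shSlpi-2 libraries were chosen only after seeing the data; the other settings were planned. The planned edgeR and DESeq2 tests on recovered reads were not run, and voom was run on those reads. The cause was not tested for any change below unless stated.

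With no filter on low counts 22241 genes were tested, and calls were 1632 for Serpine2 knockdown, 703 for shSerpine2-1, 1133 between the Serpine2 hairpins, 390 for both Serpine2 hairpins and 1342 shared. The split of higher and lower calls then moved to 3001 and 1936 for Slpi knockdown, 4862 and 2492 for shSlpi-2, 1024 and 1648 for Serpine2 against Slpi, and 1367 and 1953 between the Slpi hairpins. With only the libraries compared, calls were 4176 for Serpine2 knockdown, 2592 for shSerpine2-1, 3599 between the Serpine2 hairpins, 1252 between the Slpi hairpins and 1683 for both Serpine2 hairpins. For shSlpi-2 they were 3952, against 5210 with all groups in the fit.

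With hairpin lines as units limma called 0 genes for Serpine2 knockdown (499 at unadjusted p under 0.05), 0 for Slpi knockdown (1281), 0 for Serpine2 against Slpi (419) and 0 shared. The targets, at -3.62 (adjusted p = 0.932) and -3.64 (adjusted p = 0.324), were not called either, so this fit, with fewer units, cannot show what is stable. Without both shSlpi-2 libraries calls were 2445 for shSerpine2-1, 3323 for shSlpi-1, 3185 between the Serpine2 hairpins and 1556 for both Serpine2 hairpins. For Serpine2 against Slpi, 8 lists were called. Slpi knockdown was then shSlpi-1 alone, and 2 genes were called in the direction opposite to that with all libraries. Named genes reversed without those libraries were Fbln2 for Slpi knockdown (-0.011) and, for Serpine2 against Slpi, Procr (0.00834), Plgrkt (-0.12), Lamb3 (0.17), Vegfa (-0.0332) and Pgam1 (0.00315). Of these only Lamb3 was called in its new direction (limma adjusted p = 0.0216). The others were not called (limma adjusted p from 0.268 to 0.959). With separate controls, shRenilla library A for 1 knockdown and B for the other, shared calls were 604 or 836. Rn45s between the Slpi hairpins was 0 under quantile normalization by its construction.

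With an absolute log2 fold change of at least 1, calls were by construction fewer: 50 for Serpine2 knockdown, 142 for Slpi knockdown, 75 and 105 for the Serpine2 hairpins, 85 and 312 for the Slpi hairpins, 52 for Serpine2 against Slpi, 94 and 121 between hairpins, 16 and 51 for both hairpins and 32 shared. With an estimated correlation 3, 3 and 1 lists were called for Serpine2, Slpi and Serpine2 against Slpi.

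Leaving out 1 library, where a lone library is assumed to vary like the other groups, gave 766 to 3922 calls for Serpine2 knockdown, 2401 to 5135 for Slpi knockdown, 304 to 2437 and 1610 to 4652 for the Serpine2 hairpins, 814 to 3320 and 3779 to 5509 for the Slpi hairpins, 1106 to 3436 for Serpine2 against Slpi, 404 to 3181 and 1539 to 3942 between hairpins, 167 to 1548 and 660 to 2273 for both hairpins and 631 to 2901 shared. Lists called were 9 to 11, 4 to 8 and 5 to 6. Serpine2 stayed at -3.65 to -3.59 and Slpi at -3.71 to -3.56 (highest adjusted p 1.98e-11 and 5.26e-09).

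The replicate block gave 2594, 4256 and 2149 calls for Serpine2 knockdown, Slpi knockdown and Serpine2 against Slpi. The letters do not pair the libraries, since deviations of libraries with the same letter correlated at -0.07 to 0.07 over 10 pairs of groups. Voom gave 2568, 4183 and 2194, background subtraction 2584, 4313 and 2194, deposited values 2658, 4301 and 2195, quantile normalization 2581, 4261 and 1783, and median-of-ratios scaling 2656, 4285 and 2052. The 299 pairs of named gene and comparison were followed over 24 settings, as far as a setting held them. Of these values, 6655 kept their call or lack of a call, 478 lost the call (281 of them with hairpin lines as units), 1 gained it and 7 reversed. A sign change of a value uncalled in both fits was counted as kept. A count of 0 leaves room for up to 3 reads, or 2.30 to 3.48 normalized reads, so changes below that level were not detectable at this depth.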

Other observations

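The counts below come from planned lists and contrasts, while the count of genes called in all 4 lines, the Y-linked genes, the other silent genes and the fits without both shSlpi-2 libraries were chosen only after the results were seen. With Serpine2 lowered, 37 genes of hypoxia and glycolysis gave 6 rises and 11 falls (8 and 14 adjusted over the list alone; camera adjusted p = 0.148), with the carbonic anhydrase gene Car9 at -0.73, the oxidase gene Ero1l at -0.40 and Bnip3 at -0.35. Of 30 YAP and TGF-beta target genes 8 rose and 5 fell (8 and 9 adjusted over the list alone; camera adjusted p = 0.846), with Ctgf at 0.40 and Nt5e at -0.30. Of 35 NF-kB and inflammatory cytokine genes 7 rose and 7 fell (8 and 9 adjusted over the list alone; camera adjusted p = 0.846), with the chemokine gene Cxcl5 at 0.50, and of 25 p53 target genes 6 rose and 4 fell (8 and 5 adjusted over the list alone; camera adjusted p = 0.846), with Plk2 at 0.35. Medians and means differed in sign for the YAP (0.04 and -0.03), NF-kB (0.06 and -0.06), p53 (-0.04 and 0.03), secreted angiogenic (-0.04 and 0.00) and fibroblast (-0.12 and 0.06) lists. Of markers of other cell types, 6 endothelial genes gave 0 calls by limma (Egfl7 0.44, adjusted p = 0.0932; camera adjusted p = 0.884), 4 leukocyte genes gave 0 (Itgb2 -0.08, adjusted p = 0.451; camera adjusted p = 0.846), and 5 fibroblast genes gave 1 rise and 1 fall (camera adjusted p = 0.846).

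With Slpi lowered, the iron-binding protein gene Lcn2 fell by 3.15 on the log2 scale within the NF-kB list, of which 6 rose and 11 fell (7 and 12 adjusted over the list alone; camera adjusted p = 0.471). Of 54 interferon-stimulated genes 4 rose and 8 fell (the same adjusted over the list alone; camera adjusted p = 0.471), with the peptide-loading gene Tapbp at 0.60 and Oasl2 at -0.52. Of 29 Nrf2 genes 7 rose and 8 fell (the same adjusted over the list alone; camera adjusted p = 0.579; median 0.00 and mean -0.12), with Gsta4 at -0.79 and Aldh3a1 at -1.41. Of 57 cell cycle genes 19 rose and 7 fell (22 and 7 adjusted over the list alone; camera adjusted p = 0.0529, and 0.0102 without both shSlpi-2 libraries), with Cdca8 at 0.50 and E2f1 at 0.60. The mesenchymal list, too, was called without them (adjusted p = 0.0176), but with an estimated correlation neither was (adjusted p = 0.270 for cell cycle and 0.283 for mesenchymal genes). Hypoxia genes gave 8 rises and 14 falls (camera adjusted p = 0.244), with Car9 at -0.72 and Tpi1 at 0.41, p53 target genes 7 and 4 (camera adjusted p = 0.579; median -0.04 and mean 0.03), YAP genes 10 and 6 (camera adjusted p = 0.457; median -0.04 and mean 0.05) and basement membrane genes 7 and 4 (camera adjusted p = 0.579), with the proteoglycan gene Agrn at 0.39. Of 5 fibroblast markers 3 rose and 1 fell (camera adjusted p = 0.579), with the matrix protein gene Postn at 1.80, Col14a1 at 0.80 and Pdgfra at -0.68. Lcn2, Aldh3a1 and Postn were named as list members, and none of them met all criteria that the naming rule set for single genes. Of 6 endothelial markers 1 rose and 1 fell (camera adjusted p = 0.758), and of 4 leukocyte markers 0 rose and 1 fell (camera adjusted p = 0.924).

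Between the knockdowns, the chemokine genes Ccl2 (1.13, SE 0.10) and Cxcl5 (0.75, SE 0.07) were higher in the Serpine2 lines than in the Slpi lines. Ccl2 was named as a list member and did not meet all criteria that the naming rule set for single genes. Their NF-kB list had 12 higher and 3 lower of 35 genes (camera adjusted p = 0.125, and 0.00507 without both shSlpi-2 libraries). The stress response list (10 higher and 5 lower of 40, camera adjusted p = 0.244) was also called without both shSlpi-2 libraries (adjusted p = 2.39e-06). So were the basement membrane (adjusted p = 0.0155) and immediate early (adjusted p = 0.0454) lists, also higher with Serpine2 lowered, and the hypoxia list (adjusted p = 0.0318), which was lower, though with all libraries it pointed up (adjusted p = 0.714). With an estimated correlation these 5 lists were not called without both shSlpi-2 libraries (adjusted p from 0.169 to 0.484). The other lists not named for this comparison were not called with all libraries, with camera adjusted p from 0.125 to 0.728.

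In all 4 hairpin lines, 240 genes were called up and 258 down, among them Krt14 and Krt7 up and Tslp, Ace and Spp1 down. Over 9 single-copy genes of the Y chromosome, 0 reads were counted in 9 of the 10 libraries and 2 in shSerpine2-2 library A. The 140 genes of keratin-associated proteins, defensins and bitter taste receptors had 1.64 and 1.33 reads per coding kb in shSlpi-2 and 0.425 and 0.370 in shRenilla. At the density of receptor reads, 68.8 and 79.9 reads would have fallen on them in shSlpi-2, where 120 and 97 were counted.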
